A study of Mus musculus with 8 samples.

How the data were processed

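Total RNA of mouse bone marrow-derived macrophages was labelled with biotin and hybridised to Affymetrix whole-transcript arrays, 4 for samples given PBS and 4 for samples given hepcidin, per the labels' protocols. The deposited values are on a log2 scale and were made by the authors with RMA and affy 1.36.1, per the submitters' processing notes. RMA is a method that corrects background, brings arrays to a common distribution and summarises probes into probe sets. The probe set definition and the genome build behind it are not given in the sources used here, so no genomic coordinates are printed. Values ran from 1.73 to 13.6 and were used as deposited, with no further normalization. Ratios of genes near background are compressed on such a scale, so the changes of dim genes may be understated. Scan dates, slides and raw probe intensities were not used here.

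The table held 24973 probe sets. The platform annotation gave 24015 of them exactly 1 gene symbol and none several, and in each of these the probe set number equalled the Entrez gene number. The other 958 had no listed gene and entered only the alternative that tested all probe sets. Of the named probe sets, 23922 were matched by gene number to a RefSeq table of mouse genes (GRCm38.p6), used for names and gene types, and 93 were not. For 4 symbols with more than 1 probe set the brightest was kept, which left 24011 genes. No filter on low values was applied.

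Groups and replicate numbers were taken from the sample titles. Each gene was compared between hepcidin and PBS with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), and p-values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. Log2 changes are hepcidin minus PBS, given ± SE from this fit where no other error is named. The design, 28 gene lists (20 pathways and 8 marker lists of other cell types), the alternatives and the rule for named genes were fixed before the data were examined. Of 523 list entries, 494 were measured, 1 of them under a newer symbol, and they made up 486 distinct genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation and fry, directional and mixed, were run beside it. Members were counted past the threshold over all genes and adjusted over the list alone.

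The rule for named genes took those past the threshold and, with fewer than 5 in a direction, the genes with the smallest unadjusted p until there were 10, plus a set of iron, cytokine and early response genes named whatever their value. Per list it took the members past the threshold or the 2 with the smallest unadjusted p. Predicted genes were counted and not named (1 among the higher, 6 among the lower). This gave 83 genes. Other members of a list are named where they passed over the list alone.

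The groups share replicate numbers, so it was checked whether equal numbers pair the arrays, before the calls of the fits were compared. Across genes, the deviations from the group mean correlated at 0.344 to 0.548 between arrays with the same number and at -0.356 to 0.124 between arrays with different numbers, so each of the 4 pairs lay above the bound of 0.1 set in advance. The pairing comes from the numbers in the titles and this check, and the labels do not say what a number stands for. The median residual SD was 0.154 without and 0.119 with the number as a block.

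The fits were tested on simulated data with the 24011 genes and the spread of this comparison. Without the block, limma recovered 13.4% of log2 changes of 0.5, 95.5% of changes of 1 and 100% of changes of 2, with 1 false call among 141. With the block it recovered 82.1%, 100% and 100%, with 13 false calls among 212. The simulation held 67 genes changed by 0.5, 67 by 1 and 66 by 2, far more than passed in the real data. Many changed genes ease the adjusted threshold, so these shares do not hold for data with few changed genes. A simulated list of 25 genes shifted by 0.4 was called, and 0 of 27 random lists were called by camera, in both fits. The simulated noise was independent between genes, so this cannot show how often camera calls lists of correlated genes falsely. In the real data the estimated correlation was 0.20 in the NF-kB list and 0.71 in the interferon list.

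Other settings chosen in advance were median centring, renewed quantile normalization, cyclic loess, filters on dim genes (a mean at or above the median over genes, or at least 6), the average of probe sets of a gene, all probe sets, trend and robust variance, array weights, the replicate block as a fixed or random term, leaving out each array, the other list tests and a fold minimum of 1.5. Chosen after seeing the data were leaving out both arrays numbered 1, with and without the block, and the block joined with the filter at 6, with trend and robust variance, or with the other list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.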

Results

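Gene expression was measured on 8 Affymetrix whole-transcript arrays of primary mouse macrophages grown from bone marrow precursors with M-CSF, the growth factor that drives macrophage formation. Before lysis, 4 samples had been treated with hepcidin at 10 µg/ml for 1 h and 4 with PBS. Hepcidin is the peptide hormone that binds the iron exporter ferroportin and leads to its degradation. The labels number the samples of each group from 1 to 4 and do not say whether the numbers stand for separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. After matching to gene symbols, 24011 genes had a log2 value on each of the 8 arrays. Array medians lay between 4.87 and 4.95, and correlations between arrays, taken across genes, lay between 0.989 and 0.996. The number of arrays limits the precision. As a measure of background, 32 marker genes of B cells, T and NK cells and endothelium had a median level of 3.95 with a 90th percentile of 5.76.

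The arrays differed more by replicate number than by treatment. In a principal component analysis, the first component held 36.2% of the variance and set both arrays numbered 1 apart, at -34.5 with PBS and -25.8 with hepcidin, against 6.72 to 13.2 for the other 6 arrays. The second component held 17.3% and separated number 4 from numbers 2 and 3. In both arrays numbered 1, the list of neutrophil and precursor genes was lower than in the other arrays of the same group, with a mean difference of -0.96 on the log2 scale with PBS and -1.06 with hepcidin. The same differences were -0.93 and -0.64 for interferon-stimulated genes and -0.81 and -0.73 for genes of cholesterol synthesis and uptake. The cholesterol synthesis list was low on number 4 as well. It stood at 7.26 with PBS and 7.36 with hepcidin on number 1, at 7.47 and 7.49 on number 4, and at 8.32 to 8.43 on numbers 2 and 3.

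**Figure D1:**
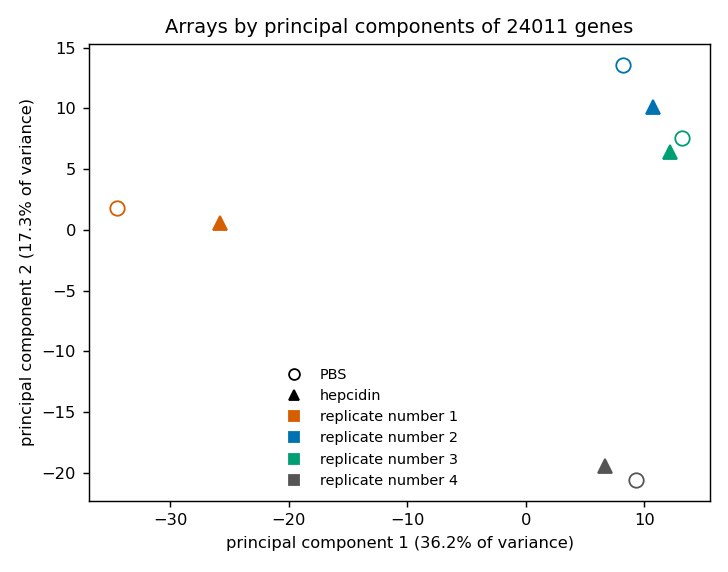
First and second principal components of 24011 genes for the 8 arrays, with the percentage of variance on each axis; open circles are PBS, filled triangles hepcidin, and colour gives the replicate number. Both arrays numbered 1 lie apart on the first component, at -34.5 and -25.8, and both numbered 4 on the second, at -20.6 and -19.4.

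The comparison of hepcidin with PBS asked which genes of these macrophages respond within 1 h. With hepcidin, the mRNA of the cytokine Tnf was higher in 4 of 4 pairs of arrays with the same number. So was that of several genes that NF-kB switches on, among them inhibitors of its own signalling. Tnf (Entrez gene 21926) stood at 11.67 ± 0.23 with hepcidin and 10.39 ± 0.23 with PBS (log2 value, mean ± SD, n = 4 in each group), a ratio of 2.42. The IκB family genes Nfkbiz (80859), Nfkbia (18035) and Nfkbie (18037) were 2.36-fold, 1.92-fold and 1.73-fold higher, with log2 changes of 1.24 ± 0.15, 0.94 ± 0.13 and 0.79 ± 0.10 (± SE). The neutrophil chemokine gene Cxcl2 (20310) was 4.75-fold higher, the largest change among the genes named here, with 2.85-fold, 5.43-fold, 6.30-fold and 5.23-fold in pairs 1 to 4. Its PBS levels in pairs 2 to 4, 4.46 to 5.41, lay within the range of the background markers, where ratios are compressed. Its log2 change of 2.25 ran from 1.86 to 2.88 when single arrays were left out, the highest without the PBS array numbered 1. Slc40a1 (53945), which encodes ferroportin, differed by less than the spread between arrays.

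No gene passed an adjusted p of 0.05 over all genes in limma. The smallest adjusted p was 0.0762, shared by Tnf, Nfkbiz and Nfkbie. At an unadjusted p under 0.05 there were 686 genes, 319 higher and 367 lower with hepcidin. The 7 other splits of the 8 arrays that part all pairs gave 569 to 712 genes. The 1201 that chance gives holds for independent arrays, which arrays with the same number were not. The groups did not overlap for 451 genes, or 1.88%, where chance gives 2.86%, again for independent arrays. With the replicate number as a block in limma, 1 gene passed, Cxcl2, with a log2 change of 2.25 ± 0.17 (SE) and an adjusted p of 0.0405. In that fit, which takes up the differences between numbers, 1179 genes had an unadjusted p under 0.05. This is no more than the 1201 that chance gives. Without the block the SE of Cxcl2 was 0.62, and its level with PBS was 7.48 on the array numbered 1 and 4.46 to 5.41 on the other 3. Without both arrays numbered 1, Cxcl2 passed with the block (2.49 ± 0.09, adjusted p 0.00329) and 0 genes passed in limma without it, with 814 at an unadjusted p under 0.05. With the number as a random block, 5 genes passed, all higher: Tnf, Nfkbiz and Nfkbie (adjusted p 0.0169 each) and Nfkbia and Mir146 (0.0364 each), the last at levels under the background median in both groups. Among the 9274 genes with a mean level of at least 6, Tnf, Nfkbie and Nfkbiz passed (adjusted p 0.0483). Leaving out the hepcidin array numbered 2, which had the lowest hepcidin level of Nfkbiz, let Nfkbiz pass with an adjusted p of 0.000842 and Tnf with 0.048.

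Of the other genes with the smallest unadjusted p among those higher with hepcidin, Mir146, the gene of a microRNA induced by NF-kB, stood at 2.86 with PBS and 3.92 with hepcidin, both under the background median, a difference of 1.06 ± 0.16. Zc3h12a, which encodes an RNase that degrades cytokine mRNA, changed by 0.64 ± 0.12. Pde4b, a cAMP phosphodiesterase gene, changed by 0.57 ± 0.10, the pattern recognition receptor gene Tlr2 by 0.52 ± 0.11, the activation marker Cd69 by 0.51 ± 0.11 and Cdc42ep2 by 0.58 ± 0.13. Pde4b, at 4.53 with PBS and 5.10 with hepcidin, and the PBS level of Cdc42ep2, 5.25, lay within the range of the background markers. None of these 6 passed over all genes without a block. The 10 named genes with the smallest unadjusted p among those lower with hepcidin were Trav7d-3, Sprr2e, Ces1h, Cd8a, Olfr645, Adamts7, Fgf23, Olfr166, Krt18 and Olfr1311. Their log2 changes lay between -0.51 for Sprr2e and -0.27 for Krt18, and their levels with PBS between 3.08 for Trav7d-3 and 5.85 for Olfr166, in or near the range of the background markers. None of them passed over all genes.

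**Figure D2:**
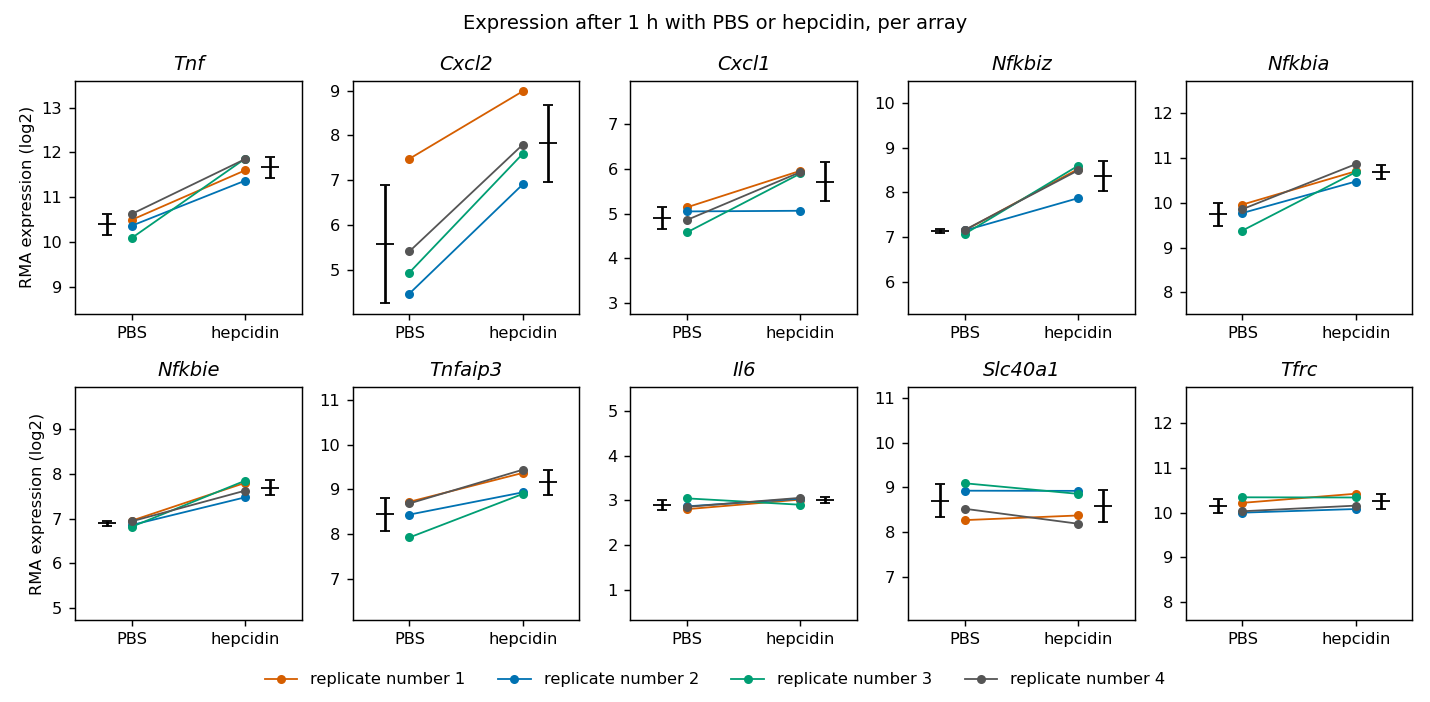
Log2 expression of 10 genes on each array after 1 h with PBS or hepcidin; lines join arrays with the same replicate number, and black bars give the mean and SD of each group (n = 4). All panels span the same number of log2 units. Tnf, Cxcl2, Cxcl1 and the NF-kB genes Nfkbiz, Nfkbia, Nfkbie and Tnfaip3 were higher with hepcidin in 4 of 4 pairs, and Slc40a1 was higher in 1 of 4.

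The genes of the NF-kB pathway and its feedback rose as a group. Of 22 measured members, 21 were higher with hepcidin, the mean log2 change was 0.41 and the median 0.35, and the mean was 0.41, 0.28, 0.60 and 0.35 in pairs 1 to 4. Adjusted over the list alone, 11 members rose, against 0 over all genes, and 18 rose with the replicate block. Besides the IκB genes these included Tnfaip3, which encodes the deubiquitinase A20, at 0.72 ± 0.19, Bcl3 at 0.61 ± 0.18, the NF-kB subunit genes Relb at 0.42 ± 0.11 and Nfkb2 at 0.39 ± 0.09, and Cd83 at 0.36 ± 0.09. Irak3 was the member below 0, at -0.04. In limma's camera, which compares a list with all other genes, the adjusted p over the 28 lists was 4.92e-29 with the preset correlation, and the adjusted p = 0.0404 with an estimated correlation. The call was lost when the block and an estimated correlation were used together (adjusted p = 0.247 with an estimated correlation). Limma's directional fry test gave an adjusted p of 0.0271 without the block and 0.104 with it. Without both arrays numbered 1, 12 members rose, adjusted over the list alone, and the adjusted p was 0.301 with an estimated correlation.

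Inflammatory cytokine and chemokine genes rose in camera with the preset correlation (adjusted p 1.49e-07), and 21 of 25 were higher with hepcidin. The adjusted p = 0.0647 with an estimated correlation did not pass, nor did the 0.155 with the block added. The mean log2 change of 0.30 lay above the median of 0.14, and the pair values ran from 0.24 to 0.41. Adjusted over the list alone, 4 members rose, against 0 over all genes: Tnf, Cxcl2, Cxcl1 (0.80 ± 0.20) and Tnfsf9, the 4-1BB ligand gene (0.43 ± 0.12). With the block, 6 rose, Cxcl10 (0.45, SE 0.11) and the prostaglandin synthase gene Ptgs2 (0.70, SE 0.16) in addition, and 1 over all genes. Cxcl1 changed by 0.01 in pair 2, and its PBS level of 4.91 lay within the range of the background markers. Without both arrays numbered 1, 2 members rose without the block and 3 with it. Il1b and Il6, cytokine genes that macrophages make on bacterial stimulation, changed by 0.23 ± 0.13 and 0.11 ± 0.08. The Il6 level of 2.89 with PBS lay below the background median.

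The list of immediate early genes, whose transcription needs no new protein, had a mean log2 change of 0.17, 22 of 27 members higher, and a camera adjusted p of 8.85e-06. That call was lost, with an adjusted p = 0.364 with an estimated correlation and 0.247 with the block as well. No member passed when adjusted over the list alone in limma, with 6 at an unadjusted p under 0.05, and 7 rose with the block: Zfp36 (0.59), Ier3 (0.61), Junb (0.44), Btg2 (0.36), Gadd45b (0.35), Maff (0.35) and Dusp5 (0.33). Fos, a component of AP-1, changed by 0.28 ± 0.31, with 3 of 4 pairs higher, and Egr1 by -0.06 ± 0.13. In limma with the block the SE of Fos was 0.10, with an unadjusted p of 0.0242 and an adjusted p over all genes of 0.967. The list of STAT3 targets and JAK-STAT feedback genes had a mean change of 0.16, 15 of 20 members higher, and a camera adjusted p of 1.68e-06. The adjusted p = 0.0647 with an estimated correlation did not pass, nor did the 0.491 with the block added. Adjusted over the list alone, the kinase gene Pim1 rose (0.46 ± 0.11), against 0 over all genes. With the block 6 rose, among them the cytokine signalling inhibitor gene Socs3 (0.38, SE 0.09) and Cebpb (0.34, SE 0.08). Without both arrays numbered 1, 1 member of the STAT3 list rose with the block. This list shares Bcl3 with the NF-kB list and Junb with the immediate early list. As many as 4 lists passed in camera in 25 of the 35 splits of the 8 arrays, the real one included, and 23 of these keep arrays with the same number together. Of the 8 splits that part all pairs, 2 gave as many, the real one included.

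Genes of iron and haem handling did not pass the test as a group. The mean log2 change of the 33 genes was 0.03, 20 of them higher, with a camera adjusted p of 0.449. Slc40a1 stood at 8.58 ± 0.36 with hepcidin and 8.70 ± 0.38 with PBS (SD, n = 4). Without the block its log2 change was -0.12 with a 95% confidence interval from -0.59 to 0.36. The SE was 0.21 without the block and 0.09 with it, where limma gave an unadjusted p of 0.239. The transferrin receptor gene Tfrc changed by 0.10 ± 0.11, the ferritin heavy chain gene Fth1 by 0.01 ± 0.07 at a level of 13.2, the haem oxygenase gene Hmox1 by 0.02 ± 0.10 and the transporter gene Slc11a1 by 0.05 ± 0.11. The ferritinophagy receptor gene Ncoa4 changed by -0.25 ± 0.21. Hamp, the hepcidin gene itself, was at 2.79 ± 0.13 (SD, n = 4) in the treated cells, below the background median. No member passed when adjusted over the list alone in limma, with 1 at an unadjusted p under 0.05. With the block 1 passed, the ferritin light chain gene Ftl1 at 0.46 (SE 0.07), whose mean level of 3.97 is that of the background markers and which passed in the same way in the NRF2 list. Limma's mixed fry test, which asks for change in either direction, gave the iron list an adjusted p of 0.957, and 0.000356 with the block. With the block it also gave 0.00149 for the T and NK cell marker list, at a mean level of 4.11. In that list, too, 1 member passed with the block when adjusted over the list alone. The value with the block therefore does not show that iron genes changed as a group.

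Macrophage identity genes had a mean log2 change of 0.07 (camera adjusted p 0.175) and inflammasome genes one of 0.08 (0.0960), and both passed with the replicate block, at 0.0328 and 0.0398. With the block these calls were lost again, at an adjusted p = 0.496 and 0.491 with an estimated correlation. Tlr2 was the identity gene that rose when adjusted over the list alone, and Adgre1, a surface marker of mature macrophages, changed by 0.09 ± 0.10. In the inflammasome list Nlrp3 (0.34) and Mefv (0.28) rose with the block, adjusted over the list alone, and Casp4 changed by 0.23 ± 0.12. The identity list was low on both arrays numbered 1 (-0.34 with PBS, -0.25 with hepcidin), and it was at 0.13 (adjusted p 0.0275) without the hepcidin and at -0.02 (0.792) without the PBS array of that number. The inflammasome list had adjusted p-values of 0.0275 without the hepcidin array numbered 1 and 0.0181 without the PBS array numbered 2. These fits, and those of the identity list without 1 array, left an array without its same-numbered partner. Without both arrays numbered 1, neither list passed with the block, at adjusted p-values of 0.343 and 0.135, and 0 inflammasome members rose with the block in limma, with 3 at an unadjusted p under 0.05.

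Interferon-stimulated genes had a mean log2 change of -0.03 (camera adjusted p 0.974), with 0.19 in pair 1 and -0.08, -0.12 and -0.12 in pairs 2 to 4. Both arrays numbered 1 had low levels of this list, so leaving out 1 of them left the other without its partner. It was lower without the PBS array numbered 1 (-0.27, adjusted p 8.7e-07), higher without the hepcidin array numbered 1 (0.13, 0.0275) and lower without both (-0.11, 0.00944). That last value had an adjusted p = 0.991 with an estimated correlation. Irf1, an interferon response gene that NF-kB also drives, changed by 0.43 ± 0.10, and the interferon gene Ifnb1 by 0.15 ± 0.08 at a level of 3.17.

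The other 12 pathway lists did not pass in camera. Mean changes were 0.06 for NRF2 and oxidative stress targets (adjusted p 0.292), 0.04 for BMP-SMAD targets (0.929), 0.03 for endoplasmic reticulum stress genes (0.929), 0.02 for heat shock genes (0.929), 0.01 for hypoxia-inducible genes (0.929) and 0.02 for alternative activation genes (0.929). They were 0.03 for cholesterol synthesis and uptake (0.929), 0.02 for cholesterol efflux and LXR targets (0.974), 0.03 for antigen presentation (0.696), 0.00 for the cell cycle (0.987), 0.01 for ribosomal proteins (0.691) and 0.03 for mitochondrial oxidative phosphorylation (0.441). The median had the opposite sign to the mean for hypoxia (-0.00) and cholesterol efflux (-0.01). The BMP target Id1 changed by 0.01 ± 0.33, Skil by 0.35 ± 0.18, the heat shock genes Dnajb1 by 0.14 ± 0.11 and Chordc1 by -0.16 ± 0.11, and the stress genes Herpud1 by 0.19 ± 0.22 and Srxn1 by 0.13 ± 0.12. Some of these lists passed when a single array was left out. Each such fit, without the block, left an array without its same-numbered partner, so differences between numbers entered the change. The NRF2 list passed without the PBS array numbered 1 (0.12, adjusted p 0.0257; -0.02 without the hepcidin array numbered 1) and without the hepcidin array numbered 3 (0.12, 0.0272). Cell cycle genes (0.13, 0.0275) and oxidative phosphorylation genes (0.06, 0.0391) passed without the hepcidin array numbered 1, and antigen presentation (0.11, 0.0435) without the PBS array numbered 4. Without the PBS array numbered 1, the cell cycle list was at -0.11 and the oxidative phosphorylation list at -0.04.

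Marker lists of other cell types did not pass in camera. The neutrophil and precursor list had a mean change of -0.05 (adjusted p 0.610) and was higher in 0 of 4 pairs. Mean changes were -0.02 for B cells (0.610), -0.04 for T and NK cells (0.605), -0.05 for erythroid cells (0.691), -0.08 for dendritic cells (0.162), 0.07 for fibroblasts and stroma (0.638, median -0.01), -0.01 for mast cells and basophils (0.929) and -0.00 for endothelium (0.974). In the T and NK cell list, Cd8a fell by 0.33 when adjusted over the list alone, at a level of 3.40 to 3.73. The neutrophil list, low on both arrays numbered 1, passed as lower without the PBS array numbered 1 (-0.29, adjusted p 0.00452) and was at 0.21 (0.183) without the hepcidin array numbered 1, and each of these fits left an array numbered 1 without its partner. It passed as lower without the hepcidin array numbered 2 (-0.19, 0.0235), and the dendritic list without the hepcidin array numbered 4 (-0.12, 0.0102).

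**Figure D3:**
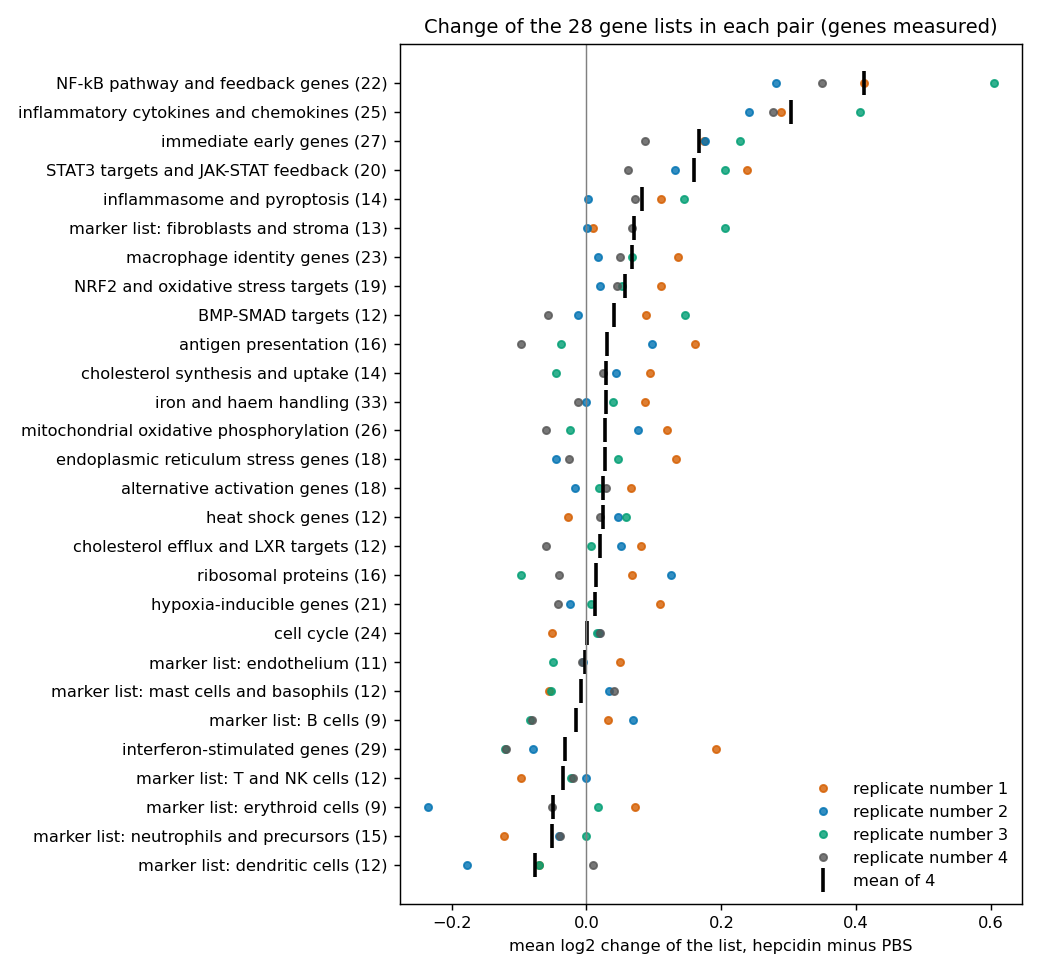
Mean log2 change, hepcidin minus PBS, of the 28 gene lists in each of the 4 pairs (coloured points) and over the pairs (black bars), with the number of genes measured in parentheses. The NF-kB list runs from 0.28 to 0.60 over the pairs, and the interferon list is above 0 in pair 1 and below 0 in the other 3.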

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

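In this part, the test of the macrophage identity list, and the margin of 1 SE applied to both tests on immature cells, were chosen only after the results were seen. For each named gene and each gene list, 222 groups of 4 arrays were searched for a single array far from the other 3, and 17 were found where chance gives about 11.1. Of these, 3 came from the PBS array numbered 1 and 1 from the hepcidin array numbered 1.

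The hepcidin array numbered 2 had a Cxcl1 level of 5.06 against 5.90 to 5.96 on the other hepcidin arrays, an Nfkbiz level of 7.87 against 8.49 to 8.60, and a mean level of the cytokine and chemokine list of 6.61 against 6.85 to 6.86. The same hepcidin array was low in the heat shock gene Chordc1, at 8.71 against 9.13 to 9.14, and in Sprr2e, at 3.70 against 3.92 to 3.94. The PBS array numbered 2 was also the lowest of its group in the cytokine list, at 6.37 against 6.45 to 6.59. The hepcidin array numbered 3 was high in Tlr2, at 7.85 against 7.47 to 7.51, and in the matrix gene Sparc, at 6.25 against 4.88 to 5.09. The hepcidin array numbered 1 was high in Cdc42ep2, at 6.22 against 5.66 to 5.75.

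Among the PBS arrays, number 1 was low in the lectin gene Clec10a, at 5.17 against 5.77 to 5.80, in Rps9, at 10.2 against 10.4 to 10.5, and in the peptide transporter gene Tap2, at 6.12 against 6.55 to 6.59. Number 2 was low in Mxi1, at 7.12 against 7.26 to 7.29, and in the fibroblast and stroma list, at 4.60 against 4.75 to 4.78. Number 3 was low in Nfkbiz, at 7.07 against 7.15 to 7.16. Number 4 was low in Cycs, at 3.80 against 4.32 to 4.41, and high in Rpl19, at 4.28 against 4.06 to 4.08, and its mean of the immediate early list was 7.70 against 7.34 to 7.40.

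Both arrays numbered 1 deviated from the other arrays of their group by over 1 on the log2 scale in the same 132 genes, 51 higher and 81 lower, where numbers 2, 3 and 4 had 18, 20 and 29 such genes. Ngp (-3.22 with PBS, -3.41 with hepcidin), Mpo (-1.89, -2.49) and Elane (-1.87, -2.06), granule genes of myeloid precursors, were lower there with the monocyte chemokine receptor gene Ccr2 (-3.45, -2.73), and the cystine transporter gene Slc7a11 (1.66, 1.96) and Saa3 (2.11, 2.27) were higher. After renewed quantile normalization 96.2% of the 132 genes still deviated. This outcome was nearly fixed, since RMA had already brought the arrays to a common distribution, so it cannot decide on array scaling. The upper quartile was 7.36 on the PBS and 7.47 on the hepcidin array numbered 1, and 7.45 to 7.49 on the others. Such differences in the deposited values are small beside deviations of over 1. Fewer immature myeloid cells in these samples could account for the lower precursor genes. The median of a second precursor list of 14 genes was -0.19 with PBS and -0.21 with hepcidin. It passed the bound of -0.2 against that source in 1 array, by less than its SE of 0.13. Several of its genes, among them Ms4a3 (4.32), Gfi1 (4.33) and Olfm4 (3.91), had mean levels under the background 90th percentile of 5.76, where changes are compressed. Of the brighter members, Ly6c2 (-1.40, -1.18), Cd34 (-0.96, -0.82), Lcn2 (-0.68, -0.77), Padi4 and Hp were lower and Hgf (0.29, 0.34) was higher. This median therefore cannot decide. The macrophage identity list, which such a shortage was predicted to leave level, was lower too (-0.34 with PBS, -0.25 with hepcidin, SE 0.20). Its members include the monocyte gene Ccr2, named above, Fcgr1 (-2.12, -1.61) and Cx3cr1 (-1.45, -1.62), while Marco was higher (0.92, 1.47). A few members may carry this mean, which therefore cannot decide, and this source stays open. No other biological explanation was tested, since the labels do not say what the numbers stand for.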

How the results depend on the processing

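Choices made after seeing the data were leaving out both arrays numbered 1 and each joint setting with the replicate block. The 0 genes past the threshold stayed at 0 under each rescaling, a mean at or above the median, all probe sets, averaged probe sets, trend and robust variance, array weights, a fold minimum of 1.5 and without both arrays numbered 1. It was 3 with a mean of at least 6, 1 with the replicate block, 5 with the random block, 6 with the block and a mean of at least 6, 8 with the block and trend and robust variance and 1 with the block and without both arrays numbered 1, all of them higher, and 0 to 2 when single arrays were left out. The cause was not tested for these counts. The 4 lists called by camera became 1 with an estimated correlation, 1 with directional fry, 2 with mixed fry, 0 with the block and an estimated correlation, 0 with the block and directional fry and 8 with the block and mixed fry, and 4 to 9 when single arrays were left out. These 8 were the NF-kB, immediate early and STAT3 lists (adjusted p 0.0212 each), cytokines (0.0136), iron (0.000356), NRF2 (0.00904), inflammasome (0.0482) and T and NK cells (0.00149). With the block and a mean of at least 6, camera also called the interferon-stimulated genes (-0.03, adjusted p 0.0247). The genes past the threshold with the block and a mean of at least 6 were Cxcl2, Tnf, Nfkbiz, Nfkbie, Nfkbia and Tnfaip3 (adjusted p 0.0268 in limma). With the block and trend and robust variance they were the same genes with Mir146 and Zfp36 (0.0119). The block changed no other call than these and those given in the report. Named genes kept direction and side of the threshold in 644 values with 1 array left out and 1102 values under other settings, and lists in 166 and 519. Few arrays and levels near background limit what can be seen for dim genes.

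Some results changed sign, and the cause was not tested. After median centring these were the list of mast cells and basophils (0.0062) and the endothelium list (0.012), after renewed quantile normalization Fth1 (-0.034) and the cell cycle list (-0.0082), and after cyclic loess Id1 (-0.0052) and the cell cycle list (-0.0085). The endothelium list was 0.031 in genes at or above the median level and 0.013 with a mean of at least 6, where the neutrophil list was 0.0035, both also with the block. With array weights they were Id1 (-0.060), cholesterol synthesis (-0.0068), cholesterol efflux (-0.0015) and the cell cycle (-0.0086). Without both arrays numbered 1, with or without the block, they were Id1 (-0.14), Mki67 (0.00077), hypoxia (-0.020), endoplasmic reticulum stress (-0.0080), cholesterol efflux (-0.0011), antigen presentation (-0.013), ribosomal proteins (-0.0042), oxidative phosphorylation (-0.0028) and the mast cell list (0.0068).

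With single arrays left out, the ranges that crossed 0 were Cenpe -0.34 to 0.040, Egr1 -0.15 to 0.022, Fth1 -0.016 to 0.027, H2-DMb1 -0.042 to 0.27, Hamp -0.29 to 0.00069, Hmox1 -0.032 to 0.079, Id1 -0.22 to 0.30, Mki67 -0.21 to 0.0095, Slc11a1 -0.015 to 0.13 and Slc40a1 -0.26 to 0.014. For lists they were BMP-SMAD targets -0.033 to 0.14, NRF2 and oxidative stress targets -0.021 to 0.12, alternative activation genes -0.029 to 0.069, antigen presentation -0.075 to 0.11, cell cycle -0.11 to 0.13, cholesterol efflux and LXR targets -0.094 to 0.11 and cholesterol synthesis and uptake -0.17 to 0.21. They were also endoplasmic reticulum stress genes -0.026 to 0.057, heat shock genes -0.049 to 0.099, hypoxia-inducible genes -0.052 to 0.090, interferon-stimulated genes -0.27 to 0.13 (past the threshold at both ends), macrophage identity genes -0.018 to 0.13, mitochondrial oxidative phosphorylation -0.035 to 0.062 and ribosomal proteins -0.019 to 0.041. For marker lists they were B cells -0.038 to 0.012, endothelium -0.021 to 0.024, mast cells and basophils -0.028 to 0.012 and neutrophils and precursors -0.29 to 0.21. Each of these fits left an array without its same-numbered partner.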

Other observations

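The tests of the NF-kB list against the arrays numbered 1, neutrophils (with the genes above background) and a bacterial ligand, the test of primary against secondary response genes, with its values above background, and the comparison of the NF-kB list and of the lists without the block with the 8 splits that part all pairs, were chosen only after the results were seen. Outside the fixed lists, further genes with a mean level of at least 6 were higher with hepcidin in 4 of 4 pairs. Acod1, which encodes the enzyme that makes itaconate, was 1.65-fold higher (log2 change 0.72, SE 0.13, here and in the next values from the fit with the block). The TPL2 kinase gene Map3k8 changed by 0.36 (SE 0.09), the prostaglandin E2 receptor gene Ptger4 by 0.38 (0.09), the histone demethylase gene Kdm6b by 0.33 (0.09), the caspase-8 inhibitor gene Cflar by 0.31 (0.07) and the lectin receptor gene Clec4e by 0.32 (0.08). The glucose transporter family gene Slc2a6 changed by 0.36 (0.07) and the Regnase family gene Zc3h12c by 0.50 (0.12). Lower in 4 of 4 pairs were Ass1, which encodes argininosuccinate synthase (-0.51, SE 0.11), and Evi2b (-0.61, SE 0.16). Without the block the SEs of these 10 genes ran from 0.10 for Map3k8 to 0.41 for Acod1, and the unadjusted p was 0.110 for Acod1, 0.173 for Kdm6b and 0.356 for Clec4e. These genes were picked after their values were seen, and none passed over all genes in limma, with or without the block. Others with a smaller unadjusted p in the block fit than Kdm6b (0.00734) were left out. Among them were Pgam1 (0.63, SE 0.13), Sowahc (0.39, 0.09) and Rps25 (0.425, 0.11), higher, and Rps4l (-0.33, 0.08), lower. The share of all genes higher in 4 of 4 pairs was not counted. Of the 958 probe sets without a listed gene, 0 passed in limma and 32 had an unadjusted p under 0.05.

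The higher level of the NF-kB list was set against chance and against 3 other sources. Its mean change of 0.41 was reached by 1 of 35 splits of the 8 arrays, the real one, with a highest other value of 0.32, but splits that keep arrays with the same number together are not equivalent to the real one, and the 8 that part all pairs (1 as large, highest other 0.27) are too few for a share under 0.05. It did not rest on the arrays numbered 1, since pairs 2 to 4 had a mean change of 0.41 with an SD of 0.17. More neutrophils in the treated wells stay open. The neutrophil and precursor list had a mean change of -0.050, higher in 0 of 4 pairs, but 9 of its 15 genes, S100a8 (5.72) among them, lay under the background 90th percentile. The other 6, with Mmp8 the brightest at 8.91, were higher in 2 of 4 pairs. Their mean change was 0.0035, with pair values from -0.094 to 0.13. A bacterial ligand carried by the peptide could raise the same genes, and as Ifnb1, a target of the TRIF arm of such signalling that a low dose could leave silent, changed by 0.15 ± 0.08, an effect of hepcidin itself and of a contaminant cannot be told apart here.

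A hypothesis is that the hour captured genes that respond without new protein synthesis. The mean log2 change was 0.69 for 15 textbook primary response genes and 0.07 for 13 secondary response genes, among them Il6, Il12b and Nos2, a difference of 0.62 (SD over pairs 0.26) in the same direction in 4 of 4 pairs. The exact two-sided permutation p was 0.0286, the smallest that 70 assignments can give, and 0.125 when signs were exchanged within pairs, the smallest that 16 assignments can give. Of the 13 secondary genes 6, among them these 3, and of the 15 primary genes 2 had a mean level under the background 90th percentile of 5.76, where changes are compressed; the other 7 and 13 had mean changes of 0.09 and 0.72. Both lists were written after the values of most primary genes had been seen, so the test may favour the hypothesis. The immediate early list was fixed before the data were examined and also holds genes that need no new protein. Its mean change was 0.17, below that of the primary list. It passed in camera with the preset correlation (adjusted p 8.85e-06) and not with an estimated one (0.364). The hypothesis stays open.

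Other splits of the arrays leave the remaining counts open too. For genes without the block the comparison was fixed in advance, since all 35 splits give at least the real 0. The highest other count was 304, for numbers 1 and 4 against 2 and 3, which points to a structure of the samples. As many as the real 4 lists passed in camera in 25 of 35 splits, with a highest other count of 13, and 23 of the 25 keep arrays with the same number together. The 8 splits that part all pairs are too few for a share under 0.05. Among them 2 gave as many lists as the real 4 without the block (highest other 5) and 2 as many as the real 6 with the block (highest other 6). With the block, only the real split gave as many genes as the real 1 (highest other 0). Each count of splits with as many lists includes the real one too.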
